A study of Mus musculus with 12 samples.

How the data were processed

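RNA was extracted from cultured mouse muscle stem cells sorted by the GFP of a Pax3 reporter allele and transfected with a plasmid carrying the Six2 coding DNA or with the empty plasmid, per the labels' protocols. Complementary DNA was made by SMART-Seq2, a full-length protocol for polyadenylated RNA, fragmented with Tn5 transposase and amplified by PCR, per the labels' protocols, and sequenced on a DNBSEQ-T7, per the series' design text. The library protocol as described does not mark the strand, so reads of overlapping genes on opposite strands cannot be told apart. FastQC 0.12.1, MultiQC 1.19, STAR 2.7.11a, RSEM 1.3.3 and DESeq2 1.42.0 and the mouse build GRCm38 are named per the submitters' processing notes, which give no settings in the sources used here. The values analysed are normalized counts per gene in 12 libraries, a signal on a linear scale deposited by the authors after division of each library by a size factor. Dividing each library's values by its smallest step gave whole reads for 100% of values within 1e-04 of a whole number, and the median-of-ratios size factors recomputed from those reads matched the deposited scaling. Reads per library, in units of 1e6, came to between 12.4 and 47.3, and 1 read was worth 0.553 to 2.14 normalized counts. The table held 23586 genes, and 99.8% of their identifiers matched the GENCODE annotation of GRCm38 used for positions and transcript sequences once version numbers were left out.

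Groups were taken from the sample titles: GFP-positive or GFP-negative, with control or SIX2 plasmid, 3 libraries each. The main test was chosen before the data were examined. It was limma-trend (limma 3.58.1, R 4.3.3) on log2(normalized count + 1), with all 12 libraries in a single fit of the 4 group means, two-sided moderated tests, Benjamini-Hochberg adjustment per comparison and a threshold of 0.05. Genes with at least 10 normalized counts in at least 3 libraries were tested, which left 14580 genes. Fold changes are on the log2(value + 1) scale and understate the change of low genes. The comparisons were SIX2 label against control label in each sorted population, GFP-positive against GFP-negative under each plasmid label, and the difference of the plasmid-label effect between the populations (the interaction). A fold against a group at 0 is not given.

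A set of 30 gene lists was fixed before the data were examined, and the 28 with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01, which asks whether a list's genes move apart from the other genes, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance one way, were run beside it. Six2 was left out of every list test. Genes named in the text followed a rule fixed at the same time. Six2, Pax3, Pax7, Myf5, Myod1, Myog and Six4 were always read, and the results of a few further genes chosen by the rule are not reported here. Per comparison, up to 12 higher and 12 lower genes with the largest change were taken among those past the threshold, without overlap between the groups and with a mean of at least 50 in the higher group, leaving out unnamed genes. Of each list, up to 4 called members with the smallest p were taken, or 2 as values where none was called, and for the interaction the 10 genes with the smallest adjusted p. Genes plotted (among them Hoxa11, Hoxc8 and Tbx1) and genes named as list members outside this rule were chosen after their values were seen.

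On simulated reads with known changes, the same fit recovered 57% of genes changed by 1.5-fold and 79% of those changed by 2-fold between the GFP-negative groups, with 5 false calls among 14330 genes. Between the control groups it recovered 41% and 82%, with 7 false calls among 14313 genes. In both, the changed genes were drawn from those with a mean over 50, so recovery of lower genes was not measured. No GC trend was simulated. Alternatives fixed in advance were other pseudocounts, filters and scalings (TMM and quantile), only the compared libraries in the fit, the replicate number as a block, limma library weights, leaving out each library, and edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered reads. Adjusted p values that DESeq2 left empty were kept empty and not counted as calls. Thinning of all libraries to the smallest total, removal of trends with GC content, a split of the GFP-negative control libraries between the comparisons that share them, and plasmid-label counts without the genes called between GFP labels were added after the data had been seen. No replicate pair of a group was closer than sampling noise, with a chi-square per degree of freedom between 7.39 and 48.8. Figures were drawn with matplotlib 3.10.9. The authors' RT-qPCR for Six2 was not used here.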

Results

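Bulk RNA sequencing was performed on cultured mouse muscle stem cells, the resident progenitors of skeletal muscle. The cells carried a Pax3 allele that also expresses GFP, and were sorted into GFP-positive (PAX3-positive) and GFP-negative (PAX3-negative) populations. PAX3 is a paired-box transcription factor of muscle progenitors. The sorted cells were grown in 20% serum with 4 ng/mL basic FGF and received 2 µg of a plasmid with the mouse Six2 coding sequence, which encodes a homeobox transcription factor, or of the empty plasmid. The design asks what added SIX2 changes in either population and how the populations differ. Each of the 4 groups had 3 libraries, made from at least 50000 cells per sample. Reads per library, in units of 1e6, came to 12.4 to 33.2 in the GFP-negative control group, 34.0 to 40.2 in the GFP-negative SIX2 group, 31.3 to 47.3 in the GFP-positive control group and 12.6 to 15.5 in the GFP-positive SIX2 group. The labels do not say that the 3 libraries of a group came from separate animals or cultures, so p-values measure only the spread between these libraries, technical or biological.

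The transfected gene and the sorted gene were read before any comparison. Six2 (ENSMUSG00000024134.11, GRCm38 chromosome 17, 85684277 to 85688274, minus strand) was near the detection floor in every library, with 2 to 36 reads. Its normalized counts were 4.28, 15.9 and 24.4 in GFP-negative control libraries, 22.9, 23.7 and 19.3 in GFP-negative SIX2 libraries, 5.36, 13.3 and 3.38 in GFP-positive control libraries, and 28.6, 23.4 and 6.51 in GFP-positive SIX2 libraries. The difference by plasmid label was 0.80 ± 0.68 (SE) on the log2 scale in GFP-negative libraries (limma-trend adjusted p = 0.421) and 1.26 ± 0.68 in GFP-positive libraries (adjusted p = 0.209). Six2 thus gave no check of the plasmid labels, and groups are called "labelled SIX2" or "labelled control" throughout, so that every direction below is a direction between labels. Pax3 (ENSMUSG00000004872.15, chromosome 1, 78101267 to 78197134, minus strand) had 72.2 ± 19.0 normalized counts (SD, n = 3) in GFP-positive and 71.4 ± 2.79 in GFP-negative libraries labelled control, a log2 difference of −0.01 ± 0.41 SE (limma-trend adjusted p = 0.991). In libraries labelled SIX2 it had 10.4 ± 5.69 and 16.5 ± 2.72, a log2 difference of −0.78 between GFP labels (adjusted p = 0.432). Pax3 was therefore not higher in libraries labelled GFP-positive than in those labelled GFP-negative, and fell with the SIX2 label by 2.06 ± 0.41 SE on the log2 scale in GFP-negative libraries (limma-trend adjusted p = 0.0022) and by 2.82 ± 0.41 in GFP-positive libraries (adjusted p = 0.00029). The related factor Six4 was not past the threshold in any comparison, with log2 changes by plasmid label of −0.31 in GFP-negative and 0.06 in GFP-positive libraries.

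**Figure D1:**
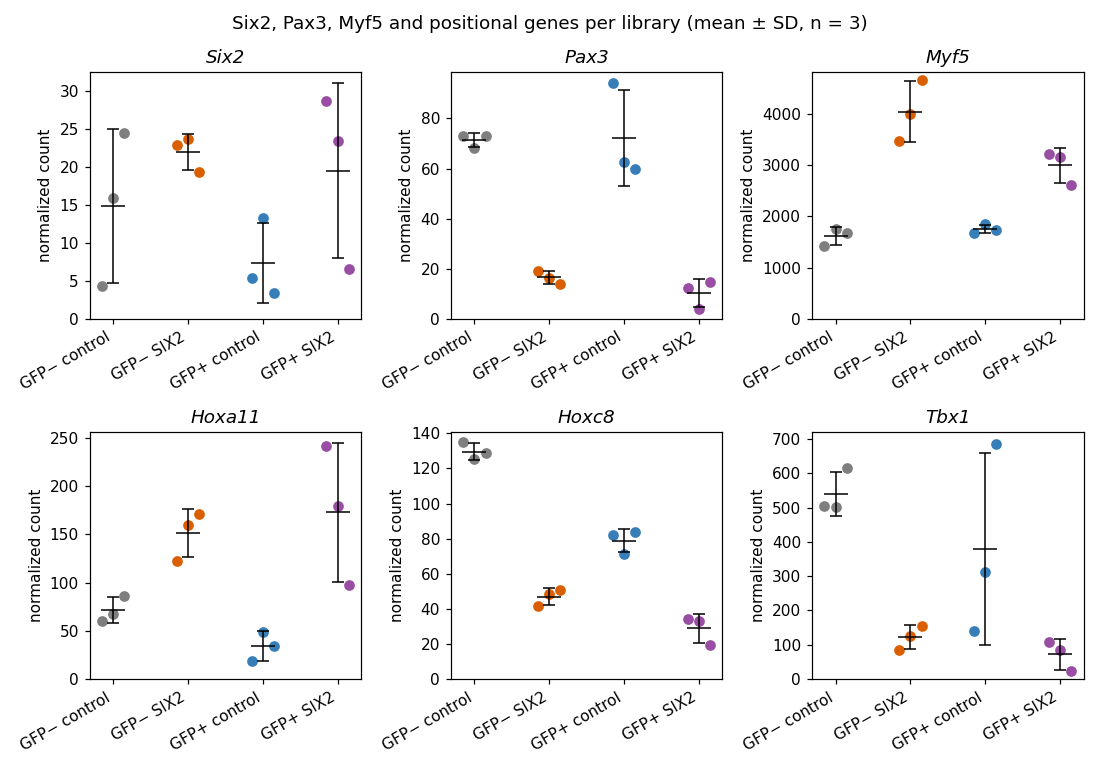
Normalized counts (linear axes) of Six2, Pax3, Myf5, Hoxa11, Hoxc8 and Tbx1 in each of the 12 libraries by group, with points for libraries and bars for mean ± SD (n = 3). Six2 does not exceed 28.6 in any library, while Pax3 has means of 71.4 and 72.2 in the control-labelled groups and 16.5 and 10.4 in the SIX2-labelled groups.

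Among libraries labelled GFP-negative, genes of the cell cycle and of the extracellular matrix were higher in those labelled SIX2 than in those labelled control. Genes of the contractile apparatus were lower. All 30 tested genes of the G2 and mitosis list rose, among them Cdc20, an activator of the anaphase-promoting complex (log2 change 1.15 ± 0.09 SE, from 1607 ± 169 to 3544 ± 178), Ccnb1, a mitotic cyclin (1.15), and Aurka, a mitotic kinase (1.13). Of 30 S phase genes, 27 rose, with Rrm2, a ribonucleotide reductase subunit, from 5563 to 12670 normalized counts, and 1 was lower. Of 39 myogenic differentiation genes, 31 were lower and none higher, including Mymx, needed for myoblast fusion (from 4056 ± 46.6 to 2288 ± 163), the troponin Tnnt1 (−0.69 on the log2 scale) and the regulatory light chain Mylpf (−0.57). Of 40 matrix genes, 21 rose and 1 fell, with Postn, a secreted matrix protein, from 232 ± 40.5 to 1051 ± 86.1 and Thbs2 from 118 to 459.

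These lists passed limma's camera test with the preset correlation and lost the call with an estimated one. Camera adjusted p was 1.5e-24 for G2 and mitosis (adjusted p = 0.0876 with an estimated correlation), 4.7e-16 for S phase (0.075), 3.05e-16 for myogenic differentiation (0.0712) and 5.84e-08 for matrix (0.267), the bracketed values being adjusted p with an estimated correlation. Adjusted over the list alone, 30 mitosis genes and 28 S phase genes were higher, 34 differentiation genes were lower, and 22 matrix genes were higher and 2 lower. The lists of the unfolded protein and integrated stress response (13 of 24 higher, 15 adjusted over the list alone), of p53 targets and CDK inhibitors (9 of 24 higher and 1 lower, 10 and 2 adjusted over the list alone) and of the interferon response (13 of 38 higher, 17 adjusted over the list alone) held under both, with camera adjusted p of 3.28e-07, 0.00247 and 0.000164, and 0.049, 0.049 and 0.036 with an estimated correlation. Trib3, a stress-induced pseudokinase, rose by 1.43, and Ccng1, a p53 target, by 0.64 on the log2 scale. Of 15 mitochondrially encoded genes, 6 were lower, 10 adjusted over the list alone (camera adjusted p = 0.00309; adjusted p = 0.352 with an estimated correlation), with mt-Nd5 at −0.96. Among factors of the myogenic lineage, Myf5 rose from 1618 ± 175 to 4042 ± 594 (limma-trend adjusted p = 6.47e-06) and Pax7, the marker of muscle stem cells, from 111 ± 33.3 to 162 ± 1.88 (adjusted p = 0.0481), Myog fell slightly (log2 −0.24, adjusted p = 0.0103) and Myod1 had a log2 change of −0.16 (adjusted p = 0.0892).

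Alx4, a homeobox factor of limb patterning, had 4.16 ± 4.37 normalized counts in GFP-negative libraries labelled control and 80.0 ± 23.1 in those labelled SIX2 (limma-trend adjusted p = 0.000371). Cavin2, a caveola coat protein, rose from 143 ± 7.51 to 1014 ± 201. Also among the 12 largest rises were P2ry14, Svep1, Pcdh19, Gria3, Prr9 and Igsf9, with log2 changes from 3.53 for P2ry14 to 2.22 for Igsf9. Gdf5, a growth factor of the BMP family, fell from 1156 ± 110 to 136 ± 41.4 (limma-trend adjusted p = 1.2e-06), and Nos1, the neuronal nitric oxide synthase, from 294 ± 16.5 to 40.8 ± 6.12. Nr2e3, a nuclear receptor, had a log2 change of −4.00, Clip4 −3.34 and Pacsin1 −2.53. Tmem158 (−3.18) and Nog, a BMP antagonist (−2.65), were high mainly in GFP-negative libraries labelled control, with means of 3164 and 655, and had smaller log2 changes in GFP-positive libraries, −1.51 for Tmem158 and −0.96 for Nog, the latter not past the threshold (limma-trend adjusted p = 0.275). Rsc1a1, with 118 ± 30.4 normalized counts against 8.29 ± 7.86, shares exon sequence with Ddi2, so its reads are uncertain. Of the 37 tested genes of positional identity, 6 were higher (Alx4, Hoxa9, Hoxa10, Hoxa11, Hoxc10 and Hoxc11) and 16 lower, among them Hoxc6 (log2 −1.40) and Emx2 (−1.49), with the same counts adjusted over the list alone and a camera adjusted p of 0.0244 (adjusted p = 0.125 with an estimated correlation). Emx2 and Hoxa11 each overlap an antisense transcript.

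In all, 4075 of 14580 genes passed the threshold between the GFP-negative groups, 1985 higher and 2090 lower with the SIX2 label, and 911 changed by over 2-fold (543 higher, 368 lower). Library weights raised the count to 6142, and without single libraries it lay between 2989 and 4301. The GFP-negative control libraries stood apart in transcripts with a window of high GC content, whose median deviation from the mean of all libraries was 0.116 to 0.144 on the log2 scale there and −0.118 to 0.062 elsewhere.

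Among libraries labelled GFP-positive, those labelled SIX2 likewise had higher cell cycle and matrix genes and lower differentiation genes. All 30 G2 and mitosis genes rose, with Ccna2, a cyclin of S phase and mitosis, from 1075 ± 18.7 to 2537 ± 215 and Ccnb1 from 1449 to 3630 normalized counts (limma-trend adjusted p = 9.17e-07 and 2.98e-06). Of 30 S phase genes, 26 rose, with Cdc6, a replication licensing factor, up by 1.66 ± 0.13 SE and Mcm3, a helicase subunit, by 1.18 on the log2 scale. Of 40 matrix genes, 26 rose, including the collagen Col1a1 from 147 ± 35.8 to 996 ± 227, Postn (log2 2.44) and Thbs2 (2.34), while 3 were lower. Of 39 differentiation genes, 27 were lower, with Klhl41, a sarcomere protein, at −0.72 and Lmod3, an actin nucleator of thin filaments, at −0.78.

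Camera adjusted p was 2.08e-26 for G2 and mitosis, 2.25e-19 for S phase, 3.13e-13 for matrix and 6.3e-15 for differentiation. The calls ended with an estimated correlation, at adjusted p = 0.0888, 0.0754, 0.119 and 0.0888. Adjusted over the list alone, 30 and 27 cycle genes were higher, 30 matrix genes higher and 3 lower, and 27 differentiation genes lower. The unfolded protein and integrated stress response (14 of 24 higher, 15 higher and 1 lower adjusted over the list alone) and p53 lists (12 of 24 higher, 12 higher and 1 lower adjusted over the list alone) held under both, with camera adjusted p of 1.62e-07 and 0.000322 and, with an estimated correlation, adjusted p = 0.0435 for each. Trib3 rose by 1.74 and Chac1, a glutathione-degrading enzyme of the stress response, by 1.26. Of 15 mitochondrially encoded genes, 9 were lower, also adjusted over the list alone (camera adjusted p = 0.000322; adjusted p = 0.249 with an estimated correlation), with mt-Nd6 at −1.30. Of 38 interferon response genes, 9 were higher and 2 lower, 9 and 3 adjusted over the list alone, and camera gave adjusted p = 0.0989. Markers of fibro-adipogenic cells, which also make matrix, had 4 of 10 genes higher and 1 lower with the SIX2 label in each population (camera adjusted p = 0.127 in GFP-negative and 0.134 in GFP-positive libraries), and 6 and 5 were higher adjusted over the list alone.

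Among the 12 largest rises were Alx4 (from 2.67 ± 1.67 to 111 ± 21.8 normalized counts; limma-trend adjusted p = 0.000191), Prr9 (log2 3.18), Avpr1a, a vasopressin receptor (3.15 ± 0.29 SE), Smpd3, a sphingomyelinase (2.90), Col1a1 (2.75) and Tap1, a peptide transporter of antigen presentation (2.42). Hoxa11, a homeobox gene of distal limb position (chromosome 6, 52242106 to 52245810), and its antisense transcript Hoxa11os rose by 2.30 and 2.27, and their reads cannot be told apart. Among the 12 largest falls were Nr2e3 (−3.92), Clip4 (−3.11), Gdf5 (from 1082 ± 50.9 to 136 ± 22.6), Pacsin1 (−2.88), Pax3, Wnt10a, a WNT ligand (−2.64), and the patterning factors Shox2 (−2.53), Tbx1 (−2.37) and Irx5 (−2.28). Of the 37 genes of positional identity, 5 were higher and 14 lower, or 6 and 15 adjusted over the list alone (camera adjusted p = 0.0266; adjusted p = 0.119 with an estimated correlation). Counting Pax3 with this list, 19 of 38 genes were called in the same direction in both plasmid-label comparisons and 0 in both GFP-label comparisons. Myf5 rose from 1754 ± 81.0 to 2995 ± 335 (limma-trend adjusted p = 0.000353), Pax7 by 0.79 (adjusted p = 0.0126), and Myog fell by 0.20 (adjusted p = 0.0339). In all, 3394 genes passed the threshold, 1760 higher and 1634 lower, and 741 changed by over 2-fold (514 higher, 227 lower). Without single libraries the count lay between 2519 and 3493.

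**Figure D2:**
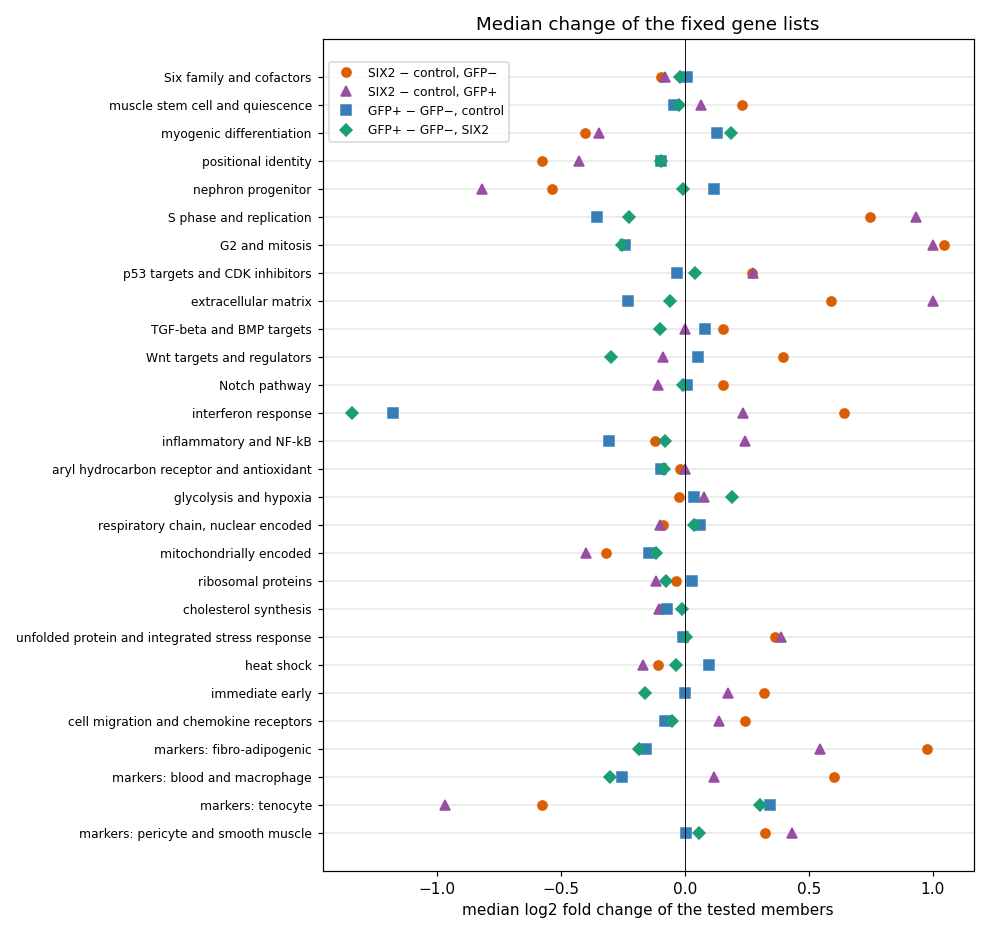
Median log2 fold change of the tested members of each fixed gene list (horizontal axis) in the 4 pairwise comparisons, 1 symbol per comparison. Cell cycle and matrix lists lie to the right and differentiation to the left for both plasmid-label comparisons, and the interferon list lies at −1.18 and −1.34 for the GFP-label comparisons.

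Across genes, the plasmid-label differences of the populations were correlated, with Pearson's r = 0.497 and Spearman's rho = 0.508 over 14579 genes without Six2, and 69.1% of genes had the same sign. Genes are not independent replicates, and the comparisons share no library. Both populations had 1082 genes called higher, against 239.6 for independent lists, and 920 called lower, against 234.2. Called in opposite directions were 7 genes higher in GFP-negative and lower in GFP-positive libraries and 3 the other way. The interaction, which tests the difference of the effects, gave 0 genes past the threshold with limma-trend (smallest adjusted p = 0.0751), 2437 genes at an unadjusted p under 0.05, 0 with edgeR and 558 with DESeq2. Among the 10 genes with the smallest p were Odc1, the rate-limiting enzyme of polyamine synthesis, the small GTPase Hras, the microtubule regulator Slain2, and Btbd1, Bri3, Rab11fip5, Ankib1, Eri3 and Sdc3. Their interaction lay between 0.90 for Btbd1 and 1.89 for Slain2 on the log2 scale. Each had its highest mean in GFP-negative libraries labelled control, for example Odc1 at 3116 ± 242 against 1133 to 1206 in the other groups. The overlapping mitochondrial gene mt-Atp8 had −1.74. The count of 0 rose to 171 without GFP-positive control library 3 and to 56 without GFP-positive SIX2 library 3, to 282 with library weights and to 6 with the trend of high-GC windows removed.

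**Figure D3:**
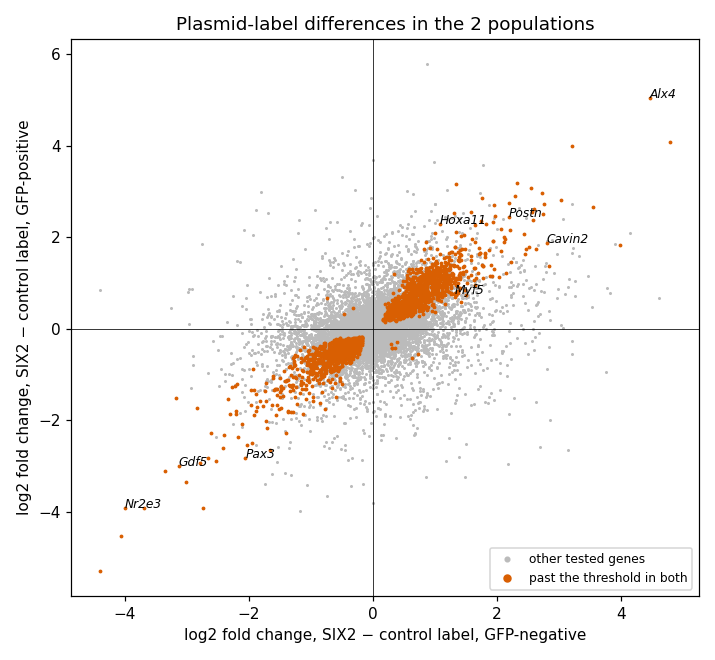
Log2 fold change of SIX2 against control label in GFP-negative libraries (horizontal axis) and in GFP-positive libraries (vertical axis) for each tested gene. Orange points, past the threshold in both, lie mostly along the diagonal, 1082 higher and 920 lower in both comparisons.

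Between the sorted populations labelled control, interferon response genes were lower in GFP-positive than in GFP-negative libraries, with the smallest camera p of the lists tested. Of 38 tested members, 14 were lower and none higher, 20 adjusted over the list alone, with camera adjusted p = 5.15e-18 and adjusted p = 0.000157 with an estimated correlation. Oasl1, an interferon-induced regulator of the antiviral response, had 17.4 ± 7.65 normalized counts against 522 ± 49.5 (limma-trend adjusted p = 5.71e-07), the ubiquitin-like Isg15 14.5 ± 2.80 against 173 ± 34.4, the chemokine Ccl5 2.46 ± 0.898 against 70.1 ± 13.5, and the viral RNA sensor Ifih1 40.1 ± 24.0 against 400 ± 48.1. The antiviral genes Oasl2, Rsad2, Ifit1 and, outside the list, Ddx60 had log2 differences from −3.50 for Oasl2 to −2.91 for Ifit1. Also outside that list, Ramp3, Yrdc (which overlaps an antisense transcript) and Suv39h2 were lower by log2 values of −3.36, −2.85 and −2.83, and Rsc1a1, with its shared sequence, by −5.88.

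Fewer and smaller differences went the other way. The largest rises among named genes were Myhas, an antisense transcript of the myosin heavy chain cluster (log2 1.14), Fbxo16 (1.13), mt-Atp8 (1.07), the histone gene H2ac18 (0.83), which has near-identical copies, and Tmsb10, an actin-binding peptide (0.80), with Cdkn1b, a CDK inhibitor, at 0.61 and Tbx3 at 0.62. Of 39 differentiation genes, 9 were higher (14 adjusted over the list alone), with Tnnc2 at 0.48. Of 30 S phase genes, 8 were lower (13 adjusted over the list alone), of 30 G2 and mitosis genes 2 (11) and of 40 matrix genes 7 (10), with Ccna2 at −0.61 and Fbn1, the fibrillin of microfibrils, at −0.90. Camera adjusted p for these lists was 7.81e-07, 7.4e-08, 1.25e-06 and 0.000162, and with an estimated correlation adjusted p = 0.316, 0.316, 0.613 and 0.613. Camera also passed heat shock genes (3 higher of 13, 4 adjusted over the list alone, adjusted p = 0.00784; adjusted p = 0.162 with an estimated correlation), with the small heat shock protein Cryab at 0.37, and inflammatory genes (2 lower of 13, 4 adjusted over the list alone, adjusted p = 0.00151; adjusted p = 0.142 with an estimated correlation).

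In all, 507 genes passed the threshold between control-labelled populations, 134 higher and 373 lower in GFP-positive libraries, 11 and 165 of them by over 2-fold. The count moved to 85, 196 and 820 without GFP-positive control library 1, 2 or 3, to 68, 187 and 174 without GFP-negative control library 1, 2 or 3, and to 314 without GFP-negative SIX2 library 2. It was 1520 with library weights, of which 37.4% were higher, 1087 with DESeq2 (38.1%) and 298 with a replicate block, against 26.4% higher in the 507. Among the protein-coding lower genes with transcript sequence, 55.0% had a 100-base window of over 79% GC, against 20.1% of the 12782 such genes tested. With the trend of such windows removed 583 genes passed, 294 higher and 289 lower.

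Between the populations labelled SIX2, interferon response genes were again lower in GFP-positive libraries. Of 38 tested members, 12 were lower in GFP-positive libraries, 31 adjusted over the list alone, with camera adjusted p = 1.42e-37 and adjusted p = 9.09e-06 with an estimated correlation. Ifit1 had 19.6 ± 7.81 normalized counts against 615 ± 43.8 and Oasl1 39.1 ± 9.85 against 946 ± 21.4 (limma-trend adjusted p = 6.72e-07 for both), Ifih1 27.2 ± 14.3 against 904 ± 33.3 and the chemokine Cxcl10 10.5 ± 3.68 against 193 ± 16.4. Tgtp2, an interferon-induced GTPase with a near-identical copy, was at 0 in all 6 GFP-positive libraries and at 55.4 ± 6.70 in this GFP-negative group. Ptn, a secreted growth factor, and Smoc2, a matrix protein, were lower by −2.81 and −1.73. Aldh4a1 and Med9 were the 2 genes called higher, with log2 differences of 0.54 and 0.42. No gene of the myogenic differentiation list passed the threshold over all genes with limma-trend, and 16 were higher adjusted over the list alone (camera adjusted p = 1.18e-15; adjusted p = 0.156 with an estimated correlation). For S phase, with 3 lower adjusted over the list alone, G2 and mitosis, with 1 lower, and glycolysis and hypoxia, with 9 higher, camera adjusted p was 6.74e-06, 3.12e-10 and 5.53e-10, and with an estimated correlation adjusted p = 0.367, 0.367 and 0.197.

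In all, 28 genes passed the threshold between the SIX2-labelled populations, 2 higher and 26 lower, and 18 of the 26 were also lower in the control-labelled comparison, against 0.7 for independent lists. Among them were 10 interferon genes, Ifitm3, Irf7, Ifih1, Ifit1, Cxcl10, Ccl5, Isg15, Oasl1, B2m and H2-D1. The count was 17 without GFP-positive SIX2 library 2, 60 (58.3% higher) without GFP-negative SIX2 library 1, 14 and 13 without GFP-negative SIX2 library 2 or 3, and 294 (64.6% higher, against 7.1%) with DESeq2. With quantile normalization 21.6% of the called genes were higher.

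**Figure D4:**
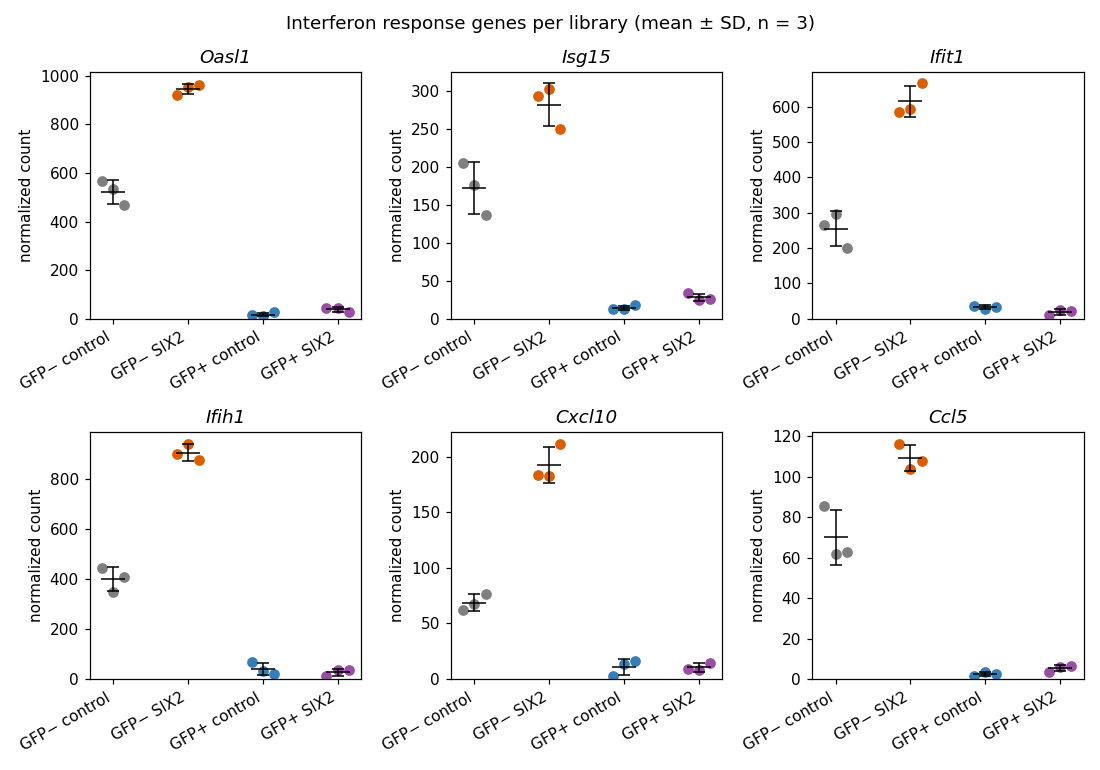
Normalized counts (linear axes) of Oasl1, Isg15, Ifit1, Ifih1, Cxcl10 and Ccl5 in each of the 12 libraries by group, with points for libraries and bars for mean ± SD (n = 3). The 6 GFP-negative libraries lie above the 6 GFP-positive libraries for each gene, with Oasl1 means of 522 and 946 against 17.4 and 39.1.

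The design also asks whether the SIX2 label moves GFP-negative cells toward GFP-positive cells. Across genes, the difference of GFP-negative libraries by plasmid label and the difference of control libraries by GFP label had a covariance of 0.114. Because both use the 3 GFP-negative control libraries, unchanged groups simulated against them gave 0.0720, an excess of 0.0420. Pearson's r was 0.336 against 0.499 simulated. The simulated r follows from noise in the shared libraries alone, and real differences in either comparison can lower r. An r below the simulated value therefore decides nothing here. The excess ranged from 0.0052 to 0.0662 without single libraries, with a leave-one-out error of 0.0452, which is as large as the excess itself. It was 0.0052 without GFP-negative control library 1 and 0.0662 without GFP-positive control library 3. Of genes called in both comparisons, 178 were lower in both, against 53.5 for independent lists, and 33 higher in both, against 18.2. In opposite directions, 59 were higher with the SIX2 label and lower in GFP-positive libraries, against 50.8, and 29 the other way, against 19.2. These overlaps use the shared controls. With the control libraries split 1 and 2 between the comparisons, so that none is shared, the covariance was 0.0542 on average over the 6 ways and lay between 0.0321 and 0.0752, though a feature common to the 3 control libraries stays in both comparisons.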

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

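The tests of explanations in this part (thinning, GC trends, blood cell transcripts and exchange of labels) were chosen and written after the results had been seen, while the test of the difference between the populations was planned. Only genes chosen by the naming rule, not all tested genes, were searched for a second look. They were picked out where all libraries of a group moved one way in one comparison and the other way in its counterpart. In a single comparison, groups did not overlap for 17.2% (GFP labels under the SIX2 label) to 46.3% (plasmid labels in GFP-negative libraries) of all tested genes. The difference between counterpart comparisons was tested for every gene, and 0 genes passed the threshold with limma-trend. The smallest adjusted p was 0.0751, and 2437 genes had an unadjusted p under 0.05. The values that follow are therefore differences of log2 changes, not calls.

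The GFP-label difference had opposite signs under the plasmid labels for the following genes. It was lower in GFP-positive libraries under the control label and higher under the SIX2 label for the Notch ligand Dll1 (0.324), the ATP synthase gene Atp5b (0.286), the vasopressin receptor Avpr1a (1.808), Hoxc5 (1.232), Btbd1 (0.904), Rab11fip5 (1.001) and the GTPase Hras (1.473). It went the other way for Wwc1, a regulator of Hippo signalling (−2.266), the TGF-beta pathway genes Smad7 (−0.553) and Skil (−0.508), mt-Atp8 (−1.743), Junb (−0.423), Id2 (−0.607) and the CDK inhibitor Cdkn1b (−0.739). The plasmid-label difference had opposite signs in the populations for Fbxo16 (−1.058), the heat shock gene Hspa1a (−0.923), Cdkn1b (−0.739), the interferon genes Ifit1 (−2.077) and Cmpk2 (−3.011) and the ribosomal gene Rpl35 (−0.729), all higher with the SIX2 label in GFP-negative libraries and lower in GFP-positive ones. For Cyc1, a subunit of respiratory complex III, the order was reversed (0.24). The glycolysis and hypoxia list differed between the populations with camera (adjusted p = 0.024, and 0.723 with an estimated correlation). Its median difference was 0.15, and no member passed the threshold over all genes. Fry did not pass this list (fry adjusted p = 0.276) and passed the interferon response list instead (fry adjusted p = 0.00066). The interferon list had a median difference of −0.196, a camera adjusted p of 0.081 and no member past the threshold.

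Pax3 and the genes of positional identity differed between the plasmid labels and not between the GFP labels, with 19 of 38 genes called in the same direction in both plasmid-label comparisons and 0 in both GFP-label comparisons. An exchange of plasmid and GFP labels could give that pattern, for example of the GFP-negative control group with the GFP-positive SIX2 group. Under that exchange both plasmid-label comparisons would instead compare the sorted populations under the same plasmid. The cell cycle, matrix, differentiation and Myf5 differences by plasmid label would then lie between sorted populations. The covariance along the GFP difference would no longer ask about a move toward GFP-positive cells. The highest Six2 count in any library, 28.6, argues against that exchange as an account of Six2 itself, which stayed near the floor under every label. Unequal depth is argued against, as 15 genes of this set were called in the same direction in both plasmid-label comparisons after thinning to 1 depth. These were not matched gene by gene to the 19. SIX2 made from the plasmid stays open, because Six2 had an adjusted p of 0.209 in GFP-positive libraries, and so do cultures of different muscle origin, which were not tested.

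In control-labelled libraries more genes were lower than higher in GFP-positive cells, 373 against 134. The windows of high GC content could account for the asymmetry, as 50.4% of called genes were higher once their trend was removed, against 26.4% before. The average trend with these windows is argued against as the whole cause of the lower genes. Of these, 276 stayed called, with a median log2 change of −0.74 after −0.90. Only a mean trend was removed, so a stronger effect on some high-GC transcripts stays open. Depth is argued against too, since 296 stayed called after thinning. Which step of library making or culture set the GFP-negative control libraries apart stays open.

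Interferon response genes were higher in GFP-negative libraries under both plasmid labels, with 10 genes called in both. The average trend with high-GC windows and depth are argued against, since all 10 stayed called after removal of that trend and all 10 after thinning. Macrophages among the GFP-negative cells are argued against, as the means of their transcripts Lyz2, Fcer1g and Adgre1 did not exceed 3.49 in either GFP-negative group, where Oasl1 reached 946. Other blood cells stay open, because of 9 abundant transcripts only 3 had values. The rest had none, while genes as low as Adgre1, with group means of at most 0.476, did have values. The level of Laptm5 would hide a small share, at 118 in GFP-negative and 99.9 in GFP-positive libraries labelled control and 101 and 107 in those labelled SIX2. Coro1a, Cd14, Cd68 and Csf1r had group means from 4.95 to 32.2, and none was called between GFP labels. A difference in handling between the sorted populations stays open and was not tested, as the labels name no batch. Under the exchange of the GFP-negative control and GFP-positive SIX2 groups considered above, the interferon difference would lie between plasmids, not between sorted populations. That exchange was not tested for these genes and stays open.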

How the results depend on the processing

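The alternatives in this part were planned except thinning, the GC trends, the split of the shared control libraries and the removal of genes called between GFP labels, which were chosen after the data had been seen. The plasmid-label comparisons held under most settings, while the counts between the control-labelled populations and of the interaction depended on single libraries and on the tool, and the cause was not tested. Library weights gave 6142 genes for the plasmid label in GFP-negative libraries in place of 4075, 1520 between control-labelled populations in place of 507, and 282 for the interaction in place of 0. DESeq2 gave 1087 between control-labelled populations, 294 in place of 28 between SIX2-labelled populations and 558 for the interaction, and edgeR gave 440, 29 and 0. Taking the replicate number as a block gave 298 between control-labelled populations and 2 lists in place of 1 for the interaction. The replicate numbers do not pair samples, as residual correlations of the 18 same-number pairs ran from −0.203 to 0.0527 and 1 of 12 libraries was closest to its own number. Removal of the trend with high-GC windows gave 6 genes for the interaction. The correlation of the plasmid-label differences rose from 0.497 to 0.65 among genes with a mean of at least 50. With an estimated correlation, camera kept 3 of 10 lists for the plasmid label in GFP-negative libraries and 2 of 14 in GFP-positive ones, 1 of 9 between control-labelled and 1 of 8 between SIX2-labelled populations, and 0 of 1 for the interaction. The fry test gave 18 lists in GFP-negative libraries and 3 between SIX2-labelled populations. For the interaction it passed the interferon response list and not the glycolysis and hypoxia list that camera passed. Without single libraries the counts lay at 2989 to 4301 for the plasmid label in GFP-negative libraries, 2519 to 3493 in GFP-positive ones, 68 to 820 between control-labelled populations (without GFP-negative control library 1 and without GFP-positive control library 3), 13 to 60 between SIX2-labelled populations (without GFP-negative SIX2 library 3 and library 1) and 0 to 171 for the interaction (171 without GFP-positive control library 3). The correlation lay at 0.415 to 0.522 and the excess covariance along the GFP difference at 0.0052 to 0.0662. With the control libraries split between the comparisons the covariance was 0.0542.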

Other observations

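Among Notch pathway genes, Notch3 and its target Heyl were higher in GFP-negative libraries labelled SIX2 (log2 1.41 and 1.03) and in GFP-positive ones (1.51 and 1.45), while Lfng, which modifies Notch receptors, was lower in both (−1.91 and −1.33). Of 12 Notch genes, 4 were higher and 4 lower in GFP-negative and 3 and 3 in GFP-positive libraries, and camera called the list in neither (adjusted p = 0.992 and 0.832). Vcam1, an adhesion molecule of muscle stem cells, rose by 1.41 and 1.63, and Nrp1, a receptor of axon and vessel guidance, by 1.39 and 1.58. Of 24 muscle stem cell genes, 8 were higher and 6 lower in GFP-negative libraries (camera adjusted p = 0.216). In GFP-positive ones 8 were higher and 2 lower (0.0428, and 0.249 with an estimated correlation). Of 19 migration genes, 8 were higher and 5 lower (camera adjusted p = 0.127), then 7 and 2 (0.0428, and 0.119 with an estimated correlation). Ccn2, a target of TGF-beta signalling, rose by 1.41 and 1.21, while of 23 TGF-beta and BMP targets 9 were higher and 5 lower in GFP-negative libraries (camera adjusted p = 0.127) and 8 higher and 7 lower in GFP-positive ones (camera adjusted p = 0.661). Cilp2, a tendon and cartilage matrix gene, fell by 2.11 and 2.07, Scx, a tendon transcription factor, by 0.51 and 0.60. Of 6 tendon markers, 2 were lower and Mkx higher (log2 1.61) in GFP-negative libraries, and 3 were lower in GFP-positive ones, where 2 were higher adjusted over the list alone (camera adjusted p = 0.127 and 0.135). Il1b, a cytokine, fell by 1.52 and 1.76.

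All splits below were run after the comparisons themselves. For each pairwise comparison the 6 libraries can be split 3 against 3 in 10 ways, which is too few for a share under 0.05. The real split alone reached its own count in each, so 1 of 10 with 4075 genes against at most 0 otherwise for the plasmid label in GFP-negative libraries, 1 of 10 with 3394 against at most 54 in GFP-positive libraries, 1 of 10 with 507 against at most 0 between control-labelled populations, and 1 of 10 with 28 against at most 1 between SIX2-labelled populations. For the correlation of the plasmid-label differences, only 1 of 100 regroupings, the real one, reached 0.497, and the next highest gave 0.351. This argues against a chance split of these libraries. It cannot exclude chance differences between cultures, as the labels do not say that the libraries of a group came from separate ones. For the interaction the real count was 0, which 100 of 100 regroupings reach by necessity, so they say nothing about chance. The highest, 5363, came from the regrouping that swaps the plasmid label of all 6 GFP-negative libraries, so it points to sample structure, the shared plasmid-label difference itself. For the excess covariance along the GFP difference, 3 of 20 labelled splits reached the real 0.0419, and the highest other gave 0.239. The 0.0419 takes off the shared noise from the fitted variance, where the 0.0420 of the comparison itself takes off the simulated noise. The 20 splits include the swap of all 6 plasmid labels, which carries the plasmid-label difference itself. They therefore cannot decide on chance, which is not excluded.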
